A study of Nothobranchius furzeri with 20 samples.

How the data were processed

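Liver RNA of male turquoise killifish (Nothobranchius furzeri, strain MZM-04/10p), an annual fish used to study ageing, was sequenced after TruSeq RNA v2 library preparation, per the labels' protocols. The 20 libraries fall into 3 groups given by age and by a swim-tunnel exercise label: 5 libraries at 9 weeks without exercise, 5 at 9 weeks with it and 10 at 27 weeks with it. The labels name no batch, day or pairing, and they do not say that each library is a separate fish, so p-values measure the spread between libraries. The labels hold no unexercised group at 27 weeks, so the joint effect of age and exercise could not be tested. The sample titles of the 27-week group carry 2 separate runs of consecutive numbers, called here the lower-numbered run (replicates 1 to 5) and the higher-numbered run (replicates 6 to 10), and both runs bear the same age and exercise labels. No condition was assigned to either run, and the runs were compared as a check of structure within one group. The exercised and the unexercised 9-week libraries also bear separate runs of title numbers. A batch that follows the titles can therefore not be told apart from exercise at 9 weeks.

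The authors deposited a table of raw counts for 26739 gene identifiers, and per the submitters' processing notes bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 were among the tools. The genome build, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes that share reads with a near-identical copy, or overlap another gene, carry that uncertainty. The counts were used as deposited. The total count per library ran from 22.4 to 44.6 M (M, mega), and 4194 identifiers had no count in any library. No pair of libraries within a group or run agreed within counting noise: over 40 pairs the lowest chi-square per degree of freedom was 44.3.

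A second table that the authors deposited as RPKM holds values treated here as a score with its own scaling. Each value equals the count divided by a gene length and by a library total, but the totals were cycled through the 20 libraries down the table instead of following the library. The gene length implied by this formula was available for 18423 genes, with a median of 2472 bp, and it differed across libraries by at most 0.00475% (CV) over the 3127 genes above 5 in all libraries. With the total of its own library, the median CV was 24.1%. Of the values above 1, 99.99% matched the cycled formula within 0.1%, and 5.00% of all values were scaled with their own library's total. The deposited values of one gene are therefore not comparable between libraries, and the counts were the basis of every main result. The implied lengths were used for classes of gene length and for RPKM recomputed with the correct totals.

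Gene names could not be attached. The files do not pair the identifiers with names, and 0 of the identifiers matched the table of RefSeq genes (assembly NfurGRZ-RIMD1) used here. The 35 gene lists fixed beforehand, the gene set tests on them and the covariate built from exocrine pancreas markers were therefore not run. The naming rule took, among genes with adjusted p under 0.05 and an average log2 CPM of 1 or more, those with a gene symbol for which every library of at least one of the groups lay on the same side of the other group's mean log2 CPM, in order of fold change. It named no gene because it required a symbol. The same rule without the symbol, stopped at 2 identifiers that rose and 2 that fell in each comparison, gave the identifiers printed, and this change was made after the data were seen.

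Genes were kept with filterByExpr and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, robust dispersion estimates, the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All 20 libraries entered one fit of the 3 groups, which share one estimate of the spread, and 17118 genes were tested. The runs of the 27-week group were compared in a fit of those 10 libraries. Standard errors of log2 fold changes were derived from the F statistic. Log2 CPM values carry a prior count of 2. CPM values are TMM-scaled and given as mean ± SD over libraries. Library measures were compared with exact permutation tests, two-sided, adjusted over 16 tests.

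The relation between the exercise and age differences was described by Pearson's r and the covariance across genes. Since both differences share the 9-week exercised libraries, the values were set beside 20 simulations of unchanged groups and beside 20 assignments that split the shared libraries 2 and 3. Genes are not independent replicates, so no p across genes is given.

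The alternatives chosen beforehand were DESeq2 1.42.0 size factors or upper-quartile scaling, no filter or a stricter filter (CPM of 1 or more in at least 5 libraries), the DESeq2 Wald test, limma 3.58.1 voom with sample weights, limma-trend on the deposited RPKM with pseudocounts of 0.1 and 1, a test against a fold of 1.5, fits of the compared groups alone, each 27-week run alone in the contrasts with 27 weeks, and leaving out each library. Alternatives chosen after the data were seen were library totals without composition scaling, recomputed RPKM, removal of each library's trend with gene length, the 27-week runs as separate sets, each run alone in the exercise fit and in the relation, fits without 27-week replicates 4 and 5, thinned counts, and removal of the 100 most abundant genes. The exercise comparison fitted on the 9-week libraries alone was planned as an alternative, and its own alternatives were added after the data were seen.

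The gene test was tested on simulated data in which 67, 67 and 66 genes were changed by folds of 1.5, 2 and 4 in counts drawn with the real means and library sizes. The spread of each gene came from fits of all 20 libraries: that of the 3 groups (common dispersion 0.183) for exercise with 3 groups and for age. For the 9-week libraries only and for the runs it came from a fit with the runs apart (0.125). The fit of the 9-week libraries had 0.094, so recovery from them alone may be understated. For exercise at 9 weeks with 3 groups in the fit, over 16932 genes, 2.99%, 29.9% and 74.2% of the genes changed by folds of 1.5, 2 and 4 were recovered. With the 9-week libraries only, over 16357 genes, these shares were 7.46%, 35.8% and 83.3%. For age, over 16909 genes, they were 8.96%, 41.8% and 90.9%, and for the 27-week runs, over 16393 genes, 7.46%, 50.7% and 93.9%. Most of the simulated 1.5-fold changes were not recovered.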

Results

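Liver transcripts were counted in 20 libraries from male killifish: 5 libraries from unexercised fish at 9 weeks, 5 from fish exercised in a swim tunnel at 9 weeks and 10 from exercised fish at 27 weeks. The design addresses how exercise changes liver expression in young fish, and how the livers of exercised fish differ between the ages. Depth was 30.3 ± 6.33 M counts (M, mega; SD, n = 5) in the unexercised group, 36.4 ± 2.24 M (SD, n = 5) in the exercised group at 9 weeks and 32.2 ± 5.79 M (SD, n = 10) at 27 weeks. Between 19738 and 20523 genes were detected per library. The 10 most abundant transcripts of each library made up 18.7% ± 2.49 of the counts in unexercised livers (SD, n = 5). Their share was 20.3% ± 1.54 in exercised livers at 9 weeks (SD, n = 5) and 23.0% ± 2.69 at 27 weeks (SD, n = 10). The share at 27 weeks exceeded the unexercised share with an exact permutation p of 0.012, adjusted p = 0.085 over the 16 library tests.

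The 27-week livers did not form one group. Their sample titles carry 2 runs of consecutive numbers under the same labels, the lower-numbered run (replicates 1 to 5) and the higher-numbered run (replicates 6 to 10). The first principal component (34.9% of the variance in log2 CPM) set the lower-numbered run apart from all other libraries. The mean of that run on this component was 91.2 ± 28.0 (SD, n = 5), against -15.9 ± 8.07 (SD, n = 5) in the higher-numbered run, -47.6 ± 6.43 (SD, n = 5) in exercised and -27.8 ± 13.1 (SD, n = 5) in unexercised livers at 9 weeks. The median correlation of log2 CPM was 0.909 between libraries of the 2 runs, below the 0.938 within the lower-numbered run and the 0.963 within the higher-numbered run. Libraries of the higher-numbered run correlated more closely with the exercised (median 0.942) and the unexercised livers at 9 weeks (median 0.944) than with the other run of their own group. The median SD over genes in log2 CPM was 0.541 across the whole 27-week group, but 0.382 within the lower-numbered and 0.319 within the higher-numbered run, against 0.271 in exercised and 0.298 in unexercised livers at 9 weeks.

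**Figure D1:**
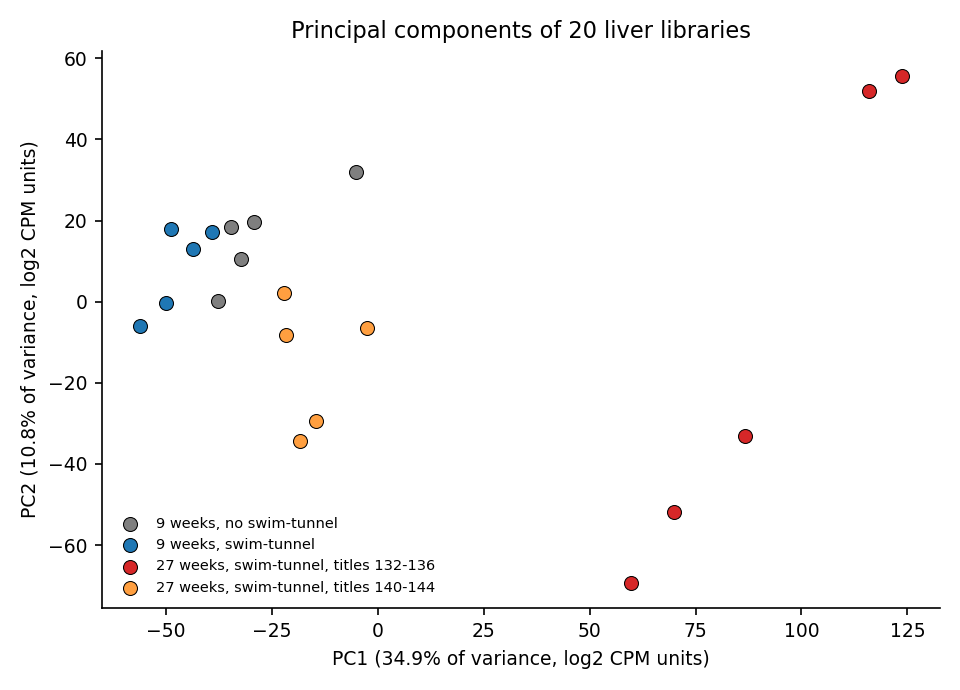
Scores of the 20 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis and colours for the groups and the title-number runs of the 27-week group. The 5 libraries of the lower-numbered run lie at 59.8 or more on the first component, and all others lie below 0.

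Exercise at 9 weeks raised 2 genes and lowered 1 in liver when all 20 libraries shared one estimate of the spread. The identifiers are not paired with gene names in the files, so these genes are given by identifier. Nfu_g_1_018732, which is among the 100 most abundant liver transcripts, rose from 2013 ± 539 to 7907 ± 1933 CPM (SD, n = 5 per group), a log2 fold change of 1.97 ± 0.26 (SE, edgeR adjusted p = 0.0045). Nfu_g_1_008170 rose from 0.69 ± 0.59 to 14.7 ± 13.1 CPM (SD, n = 5 per group), a log2 fold change of 4.40 ± 0.62 (SE, edgeR adjusted p = 0.0059) that was 3.72 without exercised replicate 1. Nfu_g_1_017417 fell from 20.9 ± 3.25 to 11 ± 0.97 CPM (SD, n = 5 per group), a log2 fold change of -0.92 ± 0.15 (SE, edgeR adjusted p = 0.024). In each of these genes, every exercised library lay beyond every unexercised one, in the direction of the change. The fall of Nfu_g_1_017417 missed the threshold in 6 of 18 alternatives (adjusted p up to 0.53) and with 7 of 10 libraries left out singly, which were exercised replicates 1, 2 and 3 (adjusted p = 0.149, 0.111 and 0.111) and unexercised replicates 2, 3, 4 and 5 (0.112, 0.055, 0.055 and 0.072). In the 27-week group Nfu_g_1_018732 had 9536 ± 3789 CPM in the lower-numbered run and 9669 ± 1063 CPM in the higher-numbered run (SD, n = 5 each), and Nfu_g_1_017417 had 12.8 ± 2.08 and 11.7 ± 2.09 CPM (SD, n = 5 each). Nfu_g_1_008170 had 37.6 ± 13.8 and 29.7 ± 6.55 CPM there (SD, n = 5 each), above its mean in exercised livers at 9 weeks, a difference that did not pass the test in either run (edgeR adjusted p = 0.057 and 0.197).

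Fitted without the 27-week libraries, the same contrast called 1261 of 16304 genes, 467 higher and 794 lower with exercise, and the 3 genes above were among them. With library totals in place of TMM 95 genes rose and 2126 fell. Of the genes over 1000 CPM in that fit, 16 of 179 rose and 0 fell with exercise, and 6 rose and 0 fell with library totals. Those of 1 to 10 CPM went the other way, with 1.83% risen and 6.35% fallen of 7311. The 100 most abundant genes, by mean CPM over all 20 libraries, shared a small upward shift. Their median log2 fold change was 0.31, and 8 of them passed the threshold. With library totals in place of TMM the median shift of these 100 genes was 0.06, so its size depended on the scaling. The TMM factor itself was 0.890 ± 0.025 in exercised and 1.06 ± 0.123 in unexercised livers (SD, n = 5 each, exact permutation p = 0.032, adjusted p = 0.127).

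The test was edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment. Of 17118 genes tested with all groups in the fit, 2045 had an unadjusted p under 0.05. The count of changed genes differed between tools and fits: the DESeq2 Wald test called 398 genes, limma-voom with sample weights 2155, and edgeR 1060 when the 27-week runs were separate sets and 73 without 27-week replicates 4 and 5. Without 1 exercised library (replicate 5) the count was 20, 9 higher and 11 lower, and without replicate 4 it was 5. In the fit of the 9-week libraries, leaving out exercised replicates 1, 2 and 3 gave 177, 315 and 320 genes, and leaving out unexercised replicates 2, 3 and 5 gave 702, 510 and 462.

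**Figure D2:**
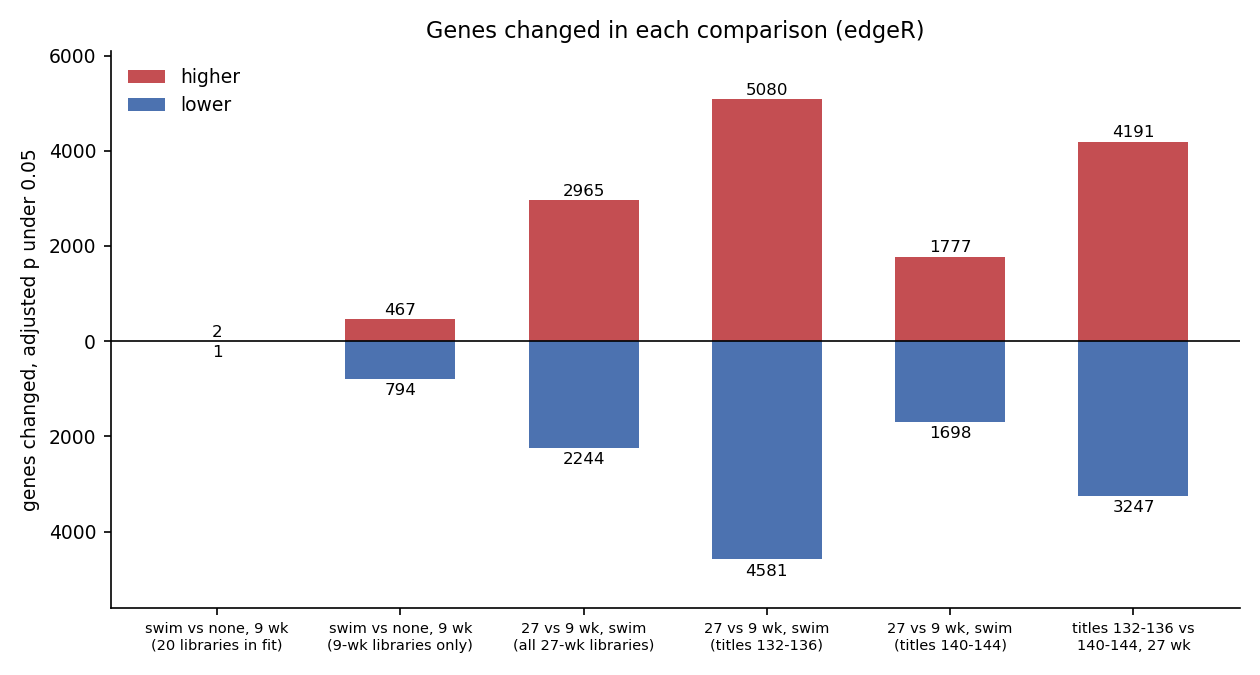
Number of genes with adjusted p under 0.05 in edgeR, higher above and lower below the zero line, for exercise at 9 weeks, for age among exercised fish and for the title-number runs of the 27-week group. The exercise count is 3 with 20 libraries in the fit and 1261 with the 9-week libraries only, and the age count is 9661 with the lower-numbered run and 3475 with the higher-numbered run.

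Among exercised fish, the livers at 27 weeks differed from those at 9 weeks in 5209 of 17118 genes, 2965 higher and 2244 lower at the older age. Nfu_g_1_000302, with the largest fall among called genes that met the naming rule, dropped from 57.4 ± 33.1 CPM at 9 weeks (SD, n = 5) to 1.56 ± 1.63 CPM at 27 weeks (SD, n = 10), a log2 fold change of -5.24 ± 0.63 (SE, edgeR adjusted p = 4.7e-05). Nfu_g_1_002545 fell from 362 ± 367 CPM (SD, n = 5) to 28.7 ± 24.7 CPM (SD, n = 10), a log2 fold change of -3.66 ± 0.79 (SE, edgeR adjusted p = 0.0025). Both fell in each run taken alone: Nfu_g_1_000302 fell by 6.62 and fell by 4.51 on the log2 scale in the lower- and higher-numbered run, and Nfu_g_1_002545 fell by 5.62 and fell by 2.85 (edgeR adjusted p of at most 0.019). Exercised 9-week replicate 3, however, had 18.6 CPM of Nfu_g_1_002545, below every library of the higher-numbered run (34.4 to 64.3 CPM). The other exercised 9-week libraries had 110 to 802 CPM.

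The 2 largest rises that met the naming rule came from the lower-numbered run. Nfu_g_1_007386 went from 3.78 ± 3.75 CPM at 9 weeks (SD, n = 5) to 1004 ± 309 CPM in that run and 7.65 ± 9.47 CPM in the higher-numbered run (SD, n = 5 each). Over the whole 27-week group its log2 fold change was 7.06 ± 1.8 (SE, edgeR adjusted p = 0.0070), and in the higher-numbered run alone it was 1.02 with an edgeR adjusted p of 0.42. It was 7.78 without 9-week exercised replicate 4. Nfu_g_1_003368 had 0.29 ± 0.23 CPM at 9 weeks (SD, n = 5), 24.7 ± 33.8 CPM in the lower-numbered run, where 1 library reached 79.1 CPM and another stood at 0.69, and 0.60 ± 0.41 CPM in the higher-numbered run (SD, n = 5 each). Its log2 fold change was 5.43 ± 1.60 over the group (SE, edgeR adjusted p = 0.016) and 1.03 in the higher-numbered run (edgeR adjusted p = 0.30). Without 27-week replicate 5 it was 4.18 (edgeR adjusted p = 0.025). The call was lost in 8 of 16 alternatives, among them limma-voom (adjusted p = 0.116) and the fit without 27-week replicates 4 and 5 (log2 fold change 2.28, edgeR adjusted p = 0.055). That of Nfu_g_1_007386 was lost in 5 of 17, among them limma-voom (adjusted p = 0.108).

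**Figure D3:**
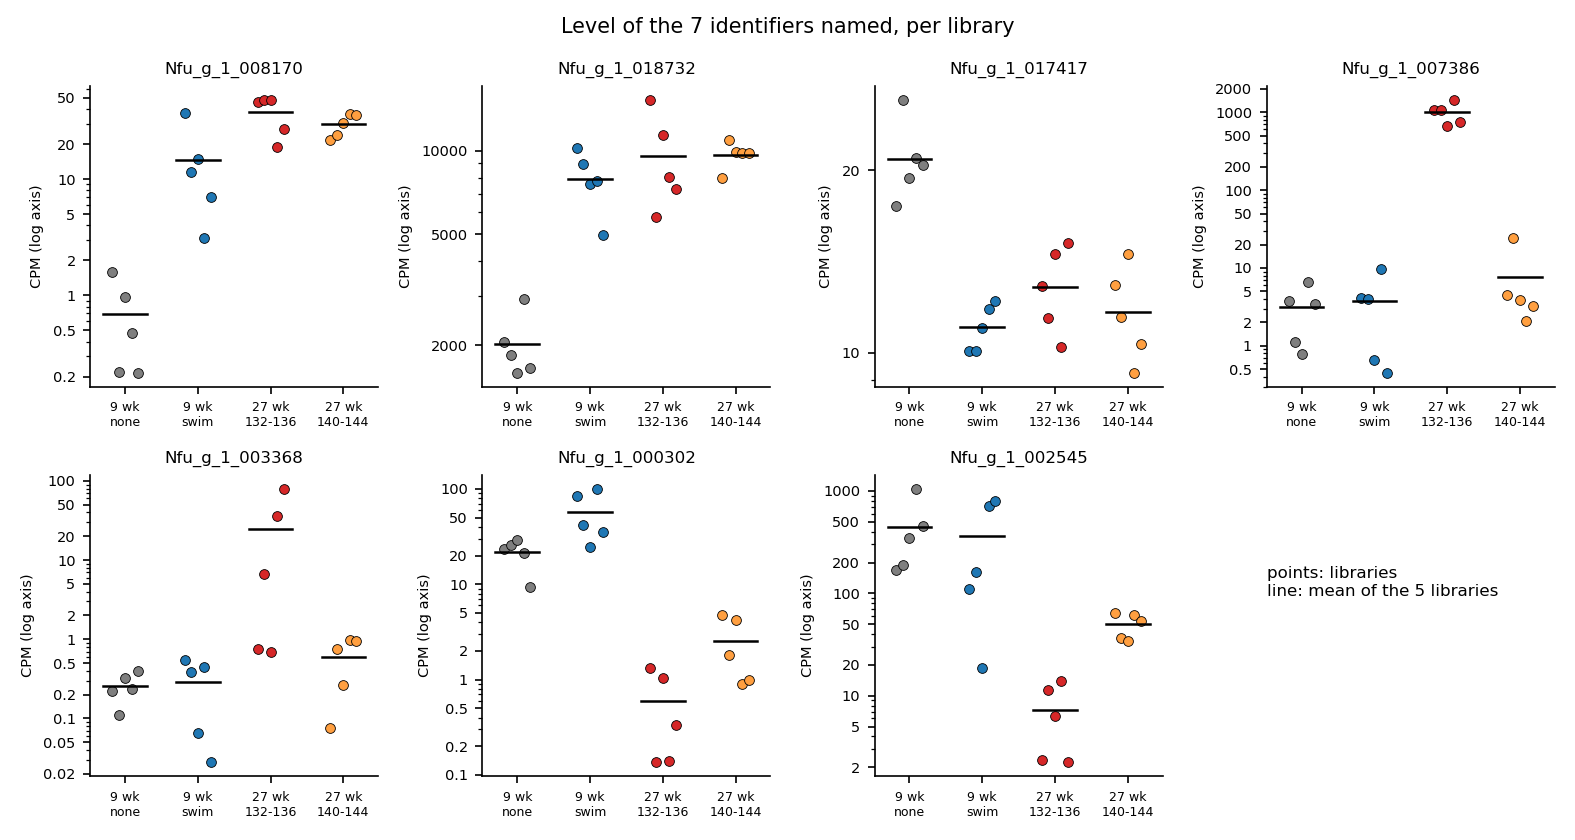
CPM of the 7 identifiers named in the text in each of the 20 libraries on log axes, by group and by title-number run of the 27-week group, with a line at the mean of each set of 5 libraries. Nfu_g_1_007386 has a mean of 1004 CPM in the lower-numbered run and between 3.11 and 7.65 CPM in the other sets, while Nfu_g_1_018732 stands at 4989 CPM or more in every exercised library.

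Each run compared with the exercised livers at 9 weeks gave its own count: 9661 of 16897 genes for the lower-numbered run, 5080 higher and 4581 lower, and 3475 of 16705 genes for the higher-numbered run, 1777 higher and 1698 lower. Among the 15995 genes tested in both, 1252 were higher and 827 lower at 27 weeks with each run, where independent lists of those sizes would share 542 and 317. Both lists share the 9-week libraries, and these genes are not independent replicates. Across them the log2 fold changes of the runs correlated with r = 0.54, against a median of 0.50 for simulated unchanged groups. That simulated r follows from the group sizes and the shared libraries, so the 2 values of r do not measure how far the runs agree. In the simulations, where genes were drawn independently, 0 genes were called higher and 0 lower with both runs. With the 9-week libraries divided between the runs, r was 0.37 (median over 20 divisions), and a median of 242.5 genes (0 to 637) were higher and 223.5 (0 to 421) lower in both, against 87.9 and 73.7 for independent lists. In the undivided comparison 123 genes went opposite ways in the 2 runs, against 829 for independent lists. With the 9-week libraries divided a median of 22 did so, against 165 for independent lists. Of the 100 most abundant genes, 65 were lower and 1 higher in the lower-numbered run, against 5 lower and 6 higher in the higher-numbered run, and 70 of them differed between the runs themselves. The share of higher calls among the age genes, 56.9% with TMM, was 73.3% with library totals, and a test against a fold of 1.5 left 891 genes.

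The livers at 27 weeks with exercise and those at 9 weeks without it, which differ in both age and exercise, were separated by 3390 of 17118 genes, 1849 higher and 1541 lower at 27 weeks. The 100 most abundant genes held 6 higher and 5 lower. The share of higher calls was 54.5% with TMM, 48.2% with upper-quartile scaling and 35.5% with library totals, so the balance of direction depended on the scaling. The lower-numbered run alone gave 8543 genes and the higher-numbered run alone 3179, and a fit of the compared groups only gave 2240. Without single unexercised libraries the count fell to 2112 (replicate 1), 1861 (replicate 3) and 1992 (replicate 5).

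Within the 27-week group, the lower-numbered run differed from the higher-numbered run in 7438 of 16157 genes, 4191 higher and 3247 lower, of which 3602 changed more than 2-fold. Abundant liver transcripts were lower in the lower-numbered run: 114 of the 160 genes over 1000 CPM fell and 2 rose, and with library totals in place of TMM 80 of 157 fell and 4 rose. Of the 796 genes of 100 to 1000 CPM 46.4% fell and 14.8% rose, a direction that turned with library totals, where 203 fell and 250 rose. Replicates 4 and 5 stood apart within the lower-numbered run by the share of counts in the 100 most abundant transcripts of each library. It was 40.0% and 39.1% in them, against 48.3% to 50.0% in replicates 1 to 3. Without replicates 4 and 5, 112 of 161 genes over 1000 CPM fell and 2 rose, and 6655 genes were called. Of these, 3177 higher and 2561 lower were among those called with replicates 4 and 5 in the fit. Genes of 1 to 10 CPM went the other way, with 1839 higher and 1064 lower of 6889. Of the 100 genes most abundant by mean CPM over all 20 libraries, 70 were lower and 0 higher, with a median log2 difference of -0.83. With library totals in place of TMM 51 of them were lower and 2 higher. The TMM factor was 1.26 ± 0.243 against 0.859 ± 0.024 (SD, n = 5 each, exact permutation p = 0.0079, the smallest this design allows, adjusted p = 0.085). The 10 most abundant transcripts of each library took 21.2% ± 2.89 of the counts in the lower-numbered run and 24.7% ± 0.29 in the higher-numbered run (SD, n = 5 each, exact permutation p = 0.016, adjusted p = 0.085). Nfu_g_1_007386 was higher in the lower-numbered run by 7.09 on the log2 scale (edgeR adjusted p = 9.9e-05). The 3 genes changed by exercise in the fit of all libraries did not pass the test between the runs (edgeR adjusted p from 0.25 to 0.96). That fit counts the difference between the runs as spread and so favours genes alike in both, which makes this no independent result. With library totals the share of higher calls was 84.6% in place of 56.3%.

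Across 17118 genes, which are not independent replicates, the exercise and age differences correlated with r = -0.50. But they share the exercised 9-week libraries, which alone gives a negative sign, and unchanged groups simulated in their place gave r = -0.58. With no change r is set by the group sizes, so the real r beside it does not show how strong the relation is. The covariance was -0.192, against -0.069 in the simulations (SD 0.0024 over 20 simulations). Genes were drawn independently there, so this SD leaves out spread between libraries that moves many genes together. The SD therefore does not test the real against the simulated values, here or by run below. The simulated spread came from the fit with the runs apart (common dispersion 0.125), and the fit of the 9-week libraries had 0.094. The simulated covariances may therefore be too large in size. With the shared libraries split 2 and 3, so that no library entered both differences, r was -0.30 (median, -0.39 to -0.15 over 20 splits) and the covariance -0.138, although anything that sets all exercised 9-week libraries apart enters both differences with opposite sign. Measured from the unexercised livers instead, the covariance of the exercise difference with the difference of the 27-week group was 0.072 against 0.069 in the simulations, and 0.012 with the unexercised libraries split (median r 0.03, -0.08 to 0.16). By run, this covariance was 0.011 against 0.068 with the lower-numbered run and 0.133 against 0.069 with the higher-numbered run. With the unexercised libraries split it was -0.035 and 0.071 (medians over 20 splits, -0.118 to 0.014 and 0.041 to 0.101).

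Over the genes called between exercised and unexercised livers in the fit of the 9-week libraries, each library was placed on a line from the unexercised mean (0) to the exercised mean (1). On the 467 genes that rose with exercise, the lower-numbered run lay at -0.045 ± 0.165 and the higher-numbered run at 0.514 ± 0.091 (SD, n = 5 each). On the 794 genes that fell, the positions were -0.167 ± 0.186 and 0.618 ± 0.191 (SD, n = 5 each). The 9-week libraries define the line and chose its genes, so their own separation on it is no test. Genes chosen for a large difference at 9 weeks tend to place other libraries nearer the middle. Positions were computed with TMM scaling only.

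**Figure D4:**
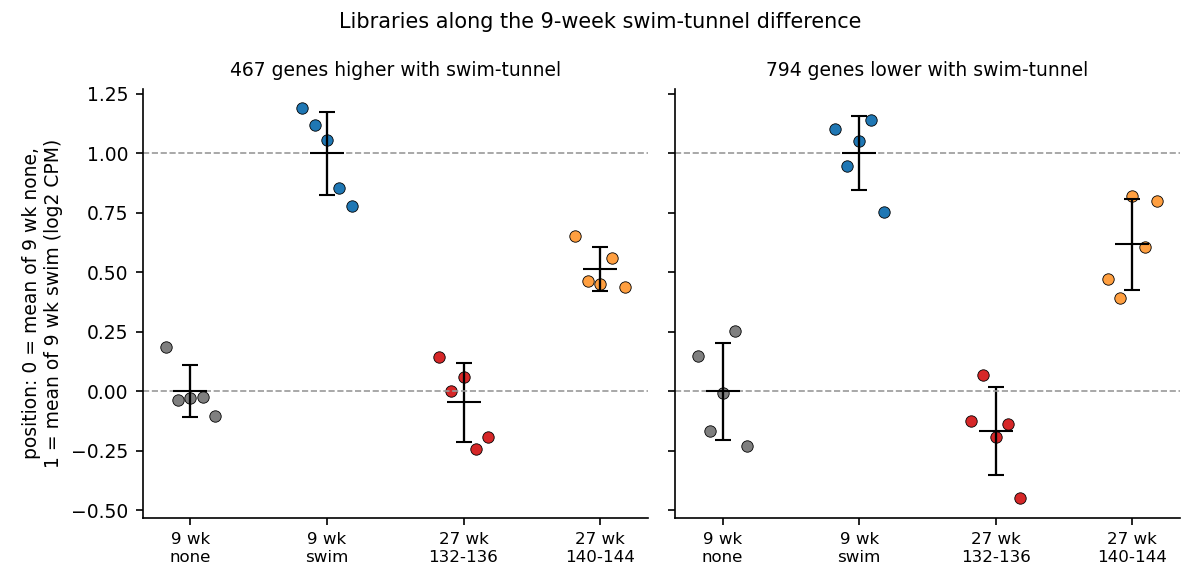
Position of each library along the difference between exercised and unexercised livers at 9 weeks, as a weighted mean of log2 CPM over 467 genes higher (left) and 794 genes lower (right) with exercise, with mean and SD of each set of 5 libraries. The higher-numbered run lies between the dashed lines that mark the unexercised (0) and exercised (1) means, and the lower-numbered run lies near 0.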

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

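The tests of the calls outside the most abundant genes, of the correlation between runs, with the runs as separate sets, without the filter on low counts, of one whole run against all other libraries, and of splits with one 27-week run at a time were chosen after the results they address were seen.

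Among the 39 groups of values examined for a single library apart from the rest, 2 held one, and about 1 in 20 is expected by chance. Unexercised replicate 2 stood at -5.12 on the first principal component, against -37.6 to -29.3 in the other 4 unexercised libraries. Unexercised replicate 5 had 9.26 CPM of Nfu_g_1_000302, against 21.3 to 29.4 CPM in the others.

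The age difference was not the same in the 2 title-number runs of the 27-week group: the test of the lower-numbered (replicates 1 to 5) against the higher-numbered run (replicates 6 to 10) called 7438 genes. Of 100 splits of the 10 libraries, 1 (the real one) gave as many, and the highest of the others gave 3. Chance is argued against, though 1 of 100 is the smallest share these splits can give. A few dominant transcripts that take the counts are argued against as the whole cause: with library totals they would move all other genes one way, but outside the 100 most abundant 1308 genes were called against the upward shift of the median gene, where false calls at the threshold allow 441. One hypothesis is that the runs differ in exercise, with one set of labels wrong. The higher-numbered run lay at 0.514 ± 0.091 (SD, n = 5) on the genes that rose, too close to the midpoint for the test to decide. The lower-numbered run lay near the unexercised mean on both gene sets. In both runs Nfu_g_1_018732, Nfu_g_1_008170 and Nfu_g_1_017417 had means nearer to the exercised than to the unexercised one, or beyond it. These 3 genes were called in a fit whose shared spread includes the difference between the runs. Such a fit favours genes that are alike in both runs, so their means cannot decide the question. A library batch that follows the title numbers cannot be told apart from a difference between fish, since each run holds 1 group only (median correlation between runs 0.909), and other sources of RNA in the samples were not tested because the identifiers carry no names.

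The count of exercise genes went from 3 to 1261 when the 27-week libraries left the fit. Entry of the spread between the 27-week runs into the shared estimate may explain it, since 1060 genes were called in the 20-library fit once the runs were separate sets. The smaller number of genes tested is argued against, as 962 were called from the 9-week libraries with no filter on low counts. For 3 of 100 splits of the 9-week libraries the fit of all groups called at least 3 genes, the real one included, and the highest other gave 89; that split set exercised replicates 1, 2 and 4 with unexercised replicates 4 and 5, which may point to a structure of these libraries other than exercise, a reading that was not tested. In the fit of the 9-week libraries, 1 of 100 splits gave 1261 genes, the real one, and the highest other gave 146. Chance is argued against in that fit. In the fit of all groups the share of 3 of 100 lies under 0.05, but the count is only 3 genes and another split gave 89. Chance is therefore not firmly excluded in the fit of all groups. The titles number the exercised and unexercised 9-week libraries in separate runs, so a batch that follows them cannot be told apart from exercise.

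For age, 1 of 100 splits gave as many as 5209 genes, the real one, and the highest other gave 4483. For 27 weeks with exercise against 9 weeks without, 2 of 100 splits gave at least 3390, the highest other 4131. These shares argue only against a free exchange of single libraries: most drawn splits mixed the runs and called 0 genes (median 0). That highest split of each contrast set 4 of the 5 libraries of the lower-numbered run on one side, and the split of that whole run against all other libraries gave 9732 and 8994 genes, more than the real groups. The higher-numbered run against all other libraries gave 706 and 2467, fewer than the real groups. There the other libraries include the distant lower-numbered run, which widens their spread, so these counts do not rank the runs. With one run at a time against 9 weeks with exercise, 1 of 100 splits (the real one) gave as many genes for each run: 9661 against a highest other of 543 for the lower-numbered and 3475 against 793 for the higher-numbered run. Against 9 weeks without exercise it was also 1 of 100, with 8543 against 1493 and 3179 against 61. Chance is thus argued against for each run, though 1 of 100 is the smallest share these splits can give. A batch that follows the runs cannot be told apart from age.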

How the results depend on the processing

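The alternatives were fixed before the data were examined, apart from the separate runs in the exercise fit, unscaled totals, recomputed RPKM, the length trend, thinning, the fits without 27-week replicates 4 and 5, removal of abundant genes, each run alone in the exercise fit and in the relation, and every alternative of the 9-week-only fit, which were chosen after seeing the data. The gene lists, their set tests and the pancreas covariate were not run, since no identifier matched a name. The cause of a shift was not tested unless stated.

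For exercise, 10 of 18 alternatives stayed within 1.5 times of 3 genes. The others gave 398 (DESeq2), 2155 (limma-voom), 1261 (9-week libraries only), 1017 and 1293 (with the lower- or the higher-numbered 27-week run alone), 1060 (runs as separate sets), 73 (without 27-week replicates 4 and 5) and 5 (recomputed RPKM, pseudocount 1); leaving out single libraries gave 2 to 20 (20 and 5 without exercised replicates 5 and 4). In the 9-week-only fit, 2421 (DESeq2), 2170 (limma-voom), 2221 with library totals (4.28% of them higher against 37.0%) and 1 against a fold of 1.5 stand beside 1261. Leaving out libraries there gave 177 to 1568: 177, 315 and 320 without exercised replicates 1, 2 and 3, and 702, 510 and 462 without unexercised replicates 2, 3 and 5.

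For age, 12 of 17 alternatives lay between 3475 and 6253 genes. The deposited RPKM gave 1663 (pseudocount 0.1) and 1590 (pseudocount 1), where the cycled totals add error by construction and the direction turned to 34.2% and 30.2% higher; recomputed RPKM at pseudocount 1 gave 3295. A fold of 1.5 left 891 and the lower-numbered run alone gave 9661. For 27 weeks with against 9 weeks without exercise, the values outside 1.5 times were 640 and 614 (deposited RPKM), 194 (fold of 1.5), 2240 (the compared groups only), 8543 (lower-numbered run) and 2242 (recomputed RPKM, pseudocount 0.1), and 1861 to 4228 without single libraries (2112, 1861 and 1992 without unexercised replicates 1, 3 and 5). The difference between the runs called 6655 to 8827 genes in all 8 alternatives and 6259 to 7442 without single libraries; thinned to the shallowest library it was 7256, so depth did not set it. The relation of exercise and age stayed at r = -0.50 to -0.45 in 3 of 4 alternatives and was -0.43 with the higher-numbered run alone.

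Library totals in place of TMM moved the median log2 fold change of all genes by -0.25 for exercise, 0.25 for age and 0.50 for the runs, so directions hold relative to TMM; of the 3 exercise genes none changed sign. No named gene changed sign in any setting. Nfu_g_1_017417 missed the threshold in 6 of 18 alternatives (adjusted p up to 0.53) and with 7 of 10 single libraries left out (exercised replicate 1, 2 or 3 or unexercised replicate 2, 3, 4 or 5; adjusted p from 0.055 to 0.149), and Nfu_g_1_007386 in 5 and Nfu_g_1_003368 in 8 alternatives, including the higher-numbered run alone. The other 4 passed in all settings, with log2 fold changes from 2.81 to 4.98 for Nfu_g_1_008170 (3.72 without exercised replicate 1), 1.73 to 2.15 for Nfu_g_1_018732, -6.62 to -3.43 for Nfu_g_1_000302 and -5.62 to -2.33 for Nfu_g_1_002545. At these depths and group sizes, and with the spread of the fit of 3 groups, simulated 1.5-fold changes were recovered in 2.99% of cases for exercise. Recovery by count was not tested, so the part that depth plays is open.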

Other observations

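The tests of the deposited RPKM and of the runs against the exercise difference were chosen after the values were seen. A candidate explanation of its scaling is library totals cycled through the 20 libraries down the table, and it passed its test: the gene length implied by that formula varied by at most 0.00475% (CV) across libraries, while scaling with each library's own total left a median CV of 24.1% and is argued against. Library totals differed up to 1.99-fold, so values of one gene carry errors of that order, and anyone who compares libraries from that table may reach other gene lists: of the 2965 genes higher with age in the counts 472 were also called from the RPKM (pseudocount 1), and of the 2244 lower genes 901. RPKM recomputed with each library's own total shared 1879 and 1089 in the same test at the same pseudocount, so part of the loss came with the change of test and scaling.

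Age calls leaned on gene length, a value with no explanation here. Of 2816 genes under 1000 bp, 600 were higher and 258 lower at 27 weeks, and of 5354 genes over 4000 bp, 683 were higher and 925 lower. With library totals the longer genes turned to 850 higher and 485 lower, while the shorter ones stood at 720 and 172, so the lean of short against long genes held under that scaling and the direction of the long genes did not. The higher-numbered run alone had 348 higher and 195 lower short genes, and 459 higher and 714 lower long genes. A lean was also present between the 2 runs, which bear the same age label. There 751 short genes were higher and 485 lower in the lower-numbered run, and 1186 long genes higher and 1164 lower. With library totals these were 1265 and 236 for short genes, and 2297 and 450 for long genes. Genes are not independent replicates, so no test across them is given.

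Within the lower-numbered run, replicates 4 and 5 had TMM factors of 1.53 and 1.51, against 1.05 to 1.16 in replicates 1 to 3, and they stood at 52.0 and 55.6 on the second principal component, where replicates 1 to 3 lay between -69.2 and -33.0. The higher-numbered run had TMM factors from 0.834 to 0.890.

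The difference between the runs ran against the exercise difference across genes (r = -0.26, no library shared), and 9 assignments of the 9-week libraries gave a correlation as large in size, an exact permutation p of 0.071.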
